A study of Mus musculus with 5 samples.

How the data were processed

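The series measured total RNA of mouse epiblast stem cells (line E3) on Illumina bead arrays. There were 5 samples with 1 array each: untreated, PD0325901 (PD), CHIR99021 (CH), LIF, and the combination of all 3 (PCL). Groups, doses and the time of 3 h were taken from the labels. Per the labels' protocols, cells were grown on inactivated CF1 mouse embryonic fibroblasts in KSR medium with 5 ng/ml FGF2. RNA was extracted with a column kit that includes DNA digestion, 400 ng was amplified with a TotalPrep kit (in vitro transcription for 12 h), and the product carried a Cy-3 label. Nothing in the labels places the samples in separate experiments or batches, and array positions are not given in the sources used here.

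The deposited scanner tables hold, per the file headers, a signal intensity for each of 25697 probes, a standard error over the beads of a probe, and a detection p-value. The intensity values are linear and differ in median between arrays, so they were treated as not normalized. The authors exported them with BeadStudio, per the submitters' processing notes, and its version is not given in the sources used here. The authors also deposited a table of processed intensity values, whole numbers from 5 upward with 12415 to 12429 empty cells per array and a median of 65 on each array. Within an array these values follow the scanner signal almost exactly in rank (Spearman's rho 0.9999). Their normalization method is not given in the sources used here, and they served as an alternative only, with empty cells and values under 16 set to 16 before log2.

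Signals were background-corrected and normalized with limma 3.58.1 in R 4.3.3. The normexp model was fitted with negative-control levels inferred from the detection p-values, with an offset of 16, followed by quantile normalization over the 5 arrays and log2. Small differences of dim genes are compressed by the offset. A probe was called detected at a detection p-value under 0.01. Gene names came from the platform annotation table. Of the probes, 23978 had 1 symbol, 0 had several and 1719 were unnamed and not analysed here by name. Gene IDs of 23962 probes matched a reference gene table, 16 did not, and 0 symbols were updated. Each of the 16593 genes was represented by its probe with the highest mean over the arrays. There were 4777 genes with more than 1 probe. No genome was used, so no coordinates are given.

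Each treatment was compared with the untreated array as a log2 difference. A gene counted when it differed by at least 2-fold and was detected on at least 1 of the 2 arrays. With 1 array per group no p-value is given for these comparisons. The error beside a value is the bead-level standard error carried to the log2 scale, and it leaves out culture, extraction and hybridisation. Where a gene was detected on 1 of the 2 arrays only, the fold is a lower bound against the lowest level detected on the other array. The number of arrays limits the precision.

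The only test between conditions was an additive limma model (lmFit and eBayes with an intensity trend) with the presence of PD, CH and LIF as 3 terms over the 5 arrays and 8353 genes. It leaves 1 residual degree of freedom, and its error is the departure of the combination from the sum of the single treatments. The prior degrees of freedom came out infinite, so genes of like intensity share 1 spread and the p-values can be extreme. The arrays are not replicate cultures. P-values were adjusted by the Benjamini-Hochberg method with a limit of 0.05. The fit was tested on simulated data with 200 altered genes in 5 runs. For PD, CH and LIF, 3.69%, 3.23% and 4.22% of calls were false, and 97.5%, 98.2% and 99.4% of the genes altered 2-fold were recovered, against 74.5%, 73.2% and 69.7% of those altered 1.5-fold. In the same runs a mean of 3.2, 2.6 and 3.8 unaltered genes per run reached 2-fold against the untreated array for PD, CH and LIF. These simulations used additive effects and equal spread, as the model assumes.

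Before the data were examined, 17 gene lists with 231 genes were fixed: FGF/ERK, Wnt/beta-catenin, LIF/STAT3, Nodal/Activin, BMP/Id and Notch targets, naive pluripotency, core pluripotency, primed epiblast, mesendoderm, neural, feeder fibroblast, stress response, interferon response, cholesterol synthesis, cell cycle and reference genes. A named probe was used for 210 of these genes, and the other 21 are not analysed here. Some genes are in several lists. A list's shift is its median log2 difference, given as a percentile among 10000 random lists of the same size matched on deciles of mean expression. It describes these arrays and is not a test between conditions. Lists with at least 2 detected members were kept, a limit lowered from 3 after the data had been seen, which concerns the neural list. In 300 simulated lists of 12 genes for CH without a shift, 7.67% fell outside the central 95%, so the nominal 5% is somewhat exceeded, and 99.3% of lists shifted by 0.3 were recognised. The number of these lists was raised after a smaller first run, in which a larger share fell outside, had been seen.

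Named genes were chosen by a rule fixed with the lists. It took, for each comparison, the 10 highest and 10 lowest genes detected on both arrays, for single treatments only if the direction was the same against the median of the 3 arrays without the agent. It added up to 3 bounded genes each way, the 5 genes each way with the lowest adjusted p of each additive term, and detected list members. Genes beyond the rule are said to be so. The alternatives were no background correction, an offset of 50, scaling to a common 75th percentile, the authors' values, other detection filters, the median over a gene's probes, a 1.5-fold limit, other references, eBayes without a trend and an adjusted p under 0.1. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 computed the lists and shares, and matplotlib 3.10.9 drew the plots.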

Results

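Gene expression was measured in mouse epiblast stem cells of the line E3, which has a hybrid genetic background. Epiblast stem cells are pluripotent cells of the primed, post-implantation kind. They were grown on a low density of growth-inactivated fibroblast feeders in a serum-replacement medium with 5 ng/ml FGF2. At semiconfluence the medium was replaced for 3 h by one of 5 media. The untreated culture received medium without supplements, so FGF2 was withdrawn there too. The other cultures received 1 uM PD0325901 (PD, an inhibitor of the ERK kinase MEK), 3 uM CHIR99021 (CH, an inhibitor of GSK3 that stabilises beta-catenin), 1000 U/ml of the cytokine LIF, or all 3 together (PCL). Each condition was measured on 1 single-colour bead array with 25697 probes, so that no comparison between 2 conditions has a replicate check.

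The 5 arrays were similar in the number of detected probes and in median signal, which do not measure RNA quality. Between 10130 and 10981 probes per array were detected, which is 39.4% to 42.7% of them, and the median signal lay between 83.3 and 91.1. The untreated array was the brightest, with a 75th percentile of 178 against 137 to 153 on the others. That percentile was 2.25 times the median of undetected probes on the untreated array, against 1.80 to 1.97 on the others. After normalization, 8353 genes were detected on at least 1 array and 6821 on all of them, and the correlation across genes between any 2 arrays was 0.986 to 0.994. The median bead-level standard error of a log2 difference was 0.115 to 0.117, and it covers the measurement on the array only. For the 6821 genes the median departure of PCL from the sum of the single treatments was 0.262 in size. If all of it were random, 1 array would have an SD of 0.14 and a difference of 2 arrays an SD of 0.19 on the log2 scale. An error is given below as the bead-level standard error (± SE, 1 array per group). The words rose and fell are used only for genes that passed an additive limma fit over the 5 arrays, in which each agent is present on 2 arrays and absent from 3.

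The comparison of PD with the untreated culture asks which transcripts depend on MEK activity within 3 h. Targets of FGF/ERK signalling were lower with PD, most of all the immediate early transcription factor Egr1 (probe ILMN_2662926), which was 12.8-fold lower (log2 difference -3.68 ± 0.13). Egr1 was highest on the untreated array, and against the median of the 3 arrays without PD its log2 difference was -2.89. The MAP kinase phosphatases Dusp4 and Dusp6 were lower by -2.24 ± 0.10 and -1.48 ± 0.06 on the log2 scale. The receptor tyrosine kinase Epha2 (-1.36), the feedback inhibitor Spry4 (-1.15) and the ETS factors Etv1 (-0.92), Etv5 (-0.81) and Etv4 (-0.69) were lower as well. In the additive fit 10 of the 18 tested FGF/ERK targets fell and 0 rose, and 12 fell when adjusted over the list alone. The 8 that did not pass included Fos (-0.34), Ier3 (-0.37) and Ccnd1 (-0.45). The median difference of the 16 list members detected on either array was -0.71, below all 10000 random lists matched on expression.

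Across all genes, 61 of 7575 were at least 2-fold different with PD, 11 higher and 50 lower. Besides the ERK targets, the lowest included the G-protein regulator Rgs16 (-1.94 ± 0.12), the activin-binding protein follistatin (Fst, -1.67 ± 0.09), the lipase inhibitor Angptl4 (-1.63 ± 0.11), Lbh (-1.51 ± 0.08), Fjx1 (-1.58) and Sox13 (-1.58), and all of these fell in the additive fit. Fjx1 and Sox13 were also lower with CH (-0.51 and -0.56) and with LIF (-0.55 and -0.54), and their PD effects in the fit were -0.98 and -1.01. Slc46a3 (-2.79) and Lor (-2.05) were among the lowest too, and they were also lower with CH (-1.56 and -1.23) and with LIF (-1.51 and -1.15). Tcf15 was not detected with PD and was at least 4.02-fold lower there. Among the genes that rose, the transcription factor Klf2 was 2.75-fold higher (1.46 ± 0.11) and the Nodal antagonist Lefty1 was 2.59-fold higher (1.38 ± 0.06). Gadd45g (1.36 ± 0.12), the small GTPase Rhob (1.32 ± 0.10), Chst15 (1.11), Fgf8 (1.03), the chemokine Cxcl12 (0.99) and the matricellular Ccn2 (0.95) rose as well. Timp3 rose (1.05 ± 0.13) on the probe used, while a second detected probe of the gene differed by -0.02. Another probe of Dusp4 differed by -0.55 and a further one by -1.85.

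The pluripotency lists did not move as a block with PD. Of 9 core pluripotency genes, Sox2 (-0.85), Utf1 (-0.70), Dppa4 (-0.66) and Tdgf1 (-0.60) fell, while Nanog rose (0.90 ± 0.08). Nanog was lowest on the untreated array, being higher also with CH (0.78), LIF (0.29) and PCL (0.88). Its PD effect in the fit was only 0.49 ± 0.11 (SE of the fit). Adjusted over the list alone, 5 fell and 1 rose. Pou5f1 differed by -0.19 ± 0.12 and did not pass. The list median of -0.31 lay at percentile 0.01 of the random lists. Of 11 naive pluripotency genes, Klf2 and Klf4 (0.85) rose and Klf5 fell (-0.92), with 3 risen and 2 fallen when adjusted over the list alone and a list median of 0.05 within the random range. Of 10 primed epiblast genes, Fgf5 (-0.88), Pou3f1 (-1.04) and Fgf15 (-0.70) fell and Fgf8 rose, with 4 and 1 when adjusted over the list alone. The Wnt/beta-catenin list had a median of -0.45 (percentile 0.01), and Tnfrsf19 (-0.93), Wnt8a (-0.63) and Lef1 fell, the last with a bound of -0.32 because it was not detected with PD, with 5 fallen when adjusted over the list alone. The LIF/STAT3 list had a median of -0.30 (percentile 0.04), and Socs3 (-0.86), Junb (-0.78) and Klf5 fell while Klf4 and Cish (0.27) rose, with 5 and 2 when adjusted over the list alone. In the stress response list Gadd45b (0.89) and Hspb1 (0.76) rose and Gadd45a fell (-1.03), and its median was 0.16 (percentile 97.6), with 3 risen and 1 fallen when adjusted over the list alone. The neural list rests on 2 detected genes, of which Sox21 rose (0.93) and Nes did not pass (0.18).

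For the PD term of the additive fit, 82 of 8353 genes rose and 169 fell at an adjusted p under 0.05 (limma, Benjamini-Hochberg). Egr1 had an effect of -2.87 ± 0.12 (SE of the fit, adjusted p = 7.14e-112), and it was lower on both arrays with PD. The fit estimated no gene-specific spread, because its prior degrees of freedom were infinite, so these p-values rank genes and do not measure variation between cultures. The share of higher genes depended on the scaling, with 43 higher and 49 lower after scaling to a common 75th percentile and 41 higher and 94 lower in the authors' values, where limma passed 0 genes for PD (630 at an unadjusted p under 0.05).

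**Figure D1:**
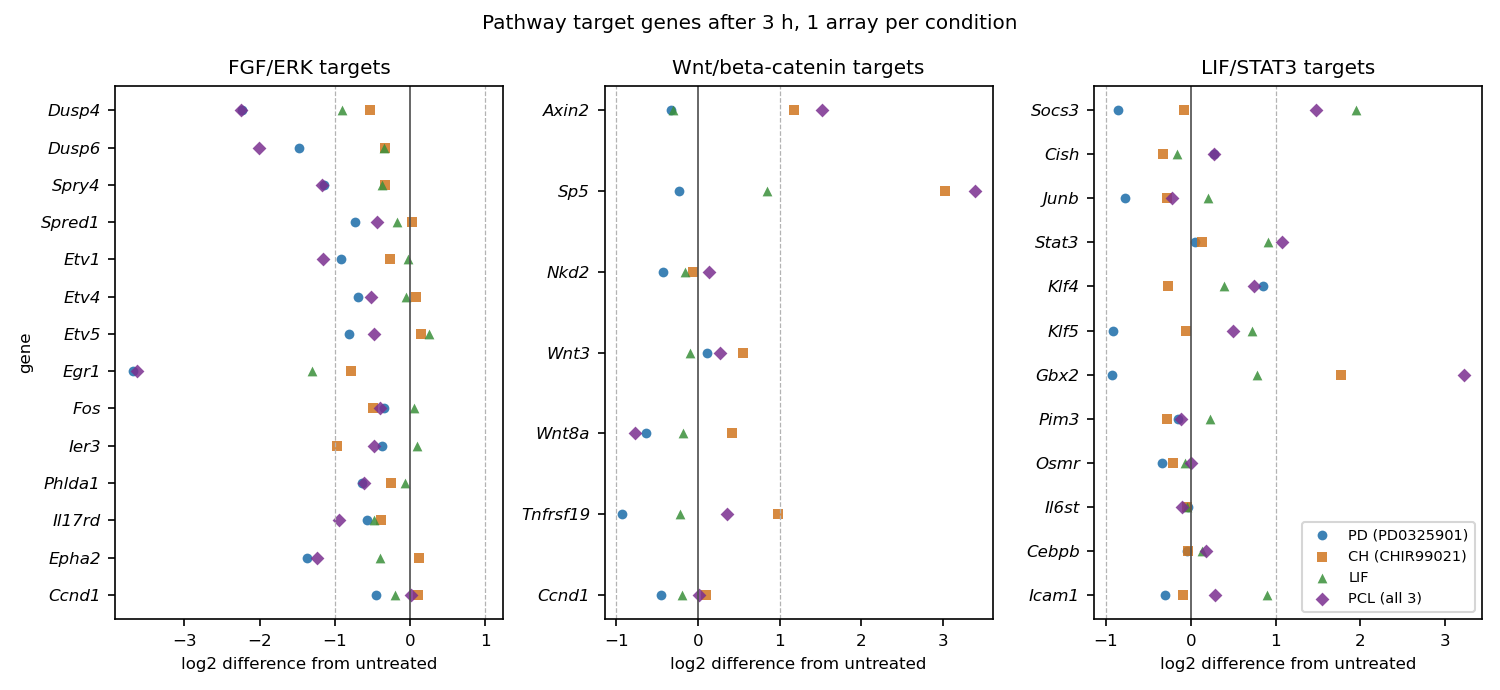
Log2 difference from the untreated array (x axis) of the members of the FGF/ERK, Wnt/beta-catenin and LIF/STAT3 lists that were detected on all 5 arrays (y axis), with 1 point per gene and treatment and dashed lines at 2-fold. Egr1 lies at -3.68 with PD and -3.62 with PCL, Sp5 at 3.03 with CH and 3.40 with PCL, and Socs3 at 1.95 with LIF and 1.48 with PCL.

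The comparison of CH with the untreated culture asks what follows GSK3 inhibition. The largest difference was in Sp5 (probe ILMN_2641201), a transcription factor gene regulated by Wnt signalling, which was 8.15-fold higher (log2 difference 3.03 ± 0.08). The homeobox gene Gbx2 was 3.41-fold higher (1.77 ± 0.13), and the Wnt feedback inhibitor Axin2 was 2.26-fold higher (1.18 ± 0.09). Primitive streak genes were higher too, namely Mixl1 (1.67 ± 0.15), Eomes (1.38 ± 0.16) and Gsc (1.02 ± 0.08). Fst was higher by 1.32 ± 0.09, opposite to its difference with PD. All 7 of these genes rose in the additive fit.

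Of 14 tested Wnt/beta-catenin targets, Axin2, Sp5, Tnfrsf19 (0.98) and Cdx2 rose and 0 fell, and 9 rose when adjusted over the list alone. Cdx2 was not detected on the untreated array, and its bound was only 0.02 with CH, against 0.63 with PCL. The list median was 0.41, above all random lists. Lef1 (0.40), Wnt3 (0.56) and Ccnd1 (0.10) did not pass over all genes. Of 11 mesendoderm genes, Eomes, Mixl1, Gsc and Fgf8 (0.90) rose and 0 fell, with 5 risen and 1 fallen when adjusted over the list alone. The mesendoderm median against untreated was 0.35, above all random lists, but the median of the additive effects was only 0.01. Foxa2 (0.14), Sox17 (0.08), Gata6 (-0.43) and Lhx1 (-0.71) did not pass. In the primed epiblast list Pou3f1 (-1.41 ± 0.09), Otx2 (-0.38) and Fgf5 (-0.27) fell and Fgf8 rose. The fit also draws on PCL, where Fgf5 was -1.79, so its call leans on the combination more than on CH alone. Adjusted over the list alone, 3 fell and 1 rose. Nanog was 0.78 ± 0.07 higher and Sox2 was -0.67 ± 0.13 lower, and neither passed.

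In all, 15 of 7882 genes were at least 2-fold different with CH, 9 higher and 6 lower. In the simulation 2.6 unaltered genes per run reached 2-fold for CH by noise alone. With the untreated array left out, so that the mean of PD and LIF was the reference, there were 20 higher and 1 lower, sharing 8 genes with the 15. Bst2, a membrane protein of the interferon response list, rose (1.62 ± 0.23), although it was also higher on every other treated array. The genes at least 2-fold lower included Slc46a3 (-1.56), Pou3f1 (-1.41), Tcf15 (-1.38) and Lor (-1.23). With PD these were lower too (-2.79, -1.04, a bound of -2.01 and -2.05). Among genes less than 2-fold lower, Ier3 (-0.97), Ndrg1 (-0.96), Rarg (-0.87), Sall2 (-0.68), Chst1 (-0.59) and the protease Prss8 (-0.56) fell. Their differences with PD were -0.37, -0.94, -0.65, -0.46, 0.29 and 0.15. The FGF/ERK list had a median of -0.26 (percentile 0.01), but in the additive fit only Ier3 of its members fell, and 1 fell and 1 rose when adjusted over the list alone. That median was 0.13 when the median of the 3 arrays without CH was the reference. The CH term had 69 genes that rose and 61 that fell over all genes, and 33 and 25 after scaling to a common 75th percentile. With that scaling 31 genes were at least 2-fold higher and 6 lower, and limma passed 0 genes for CH on the authors' values (674 at an unadjusted p under 0.05).

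The comparison of LIF with the untreated culture asks which transcripts respond to the cytokine, whose receptor activates STAT3. Socs3 (probe ILMN_2618176), the feedback inhibitor of this pathway, was 3.87-fold higher (log2 difference 1.95 ± 0.08). Stat3 itself was 0.91 ± 0.13 higher, the adhesion molecule Icam1 0.90 ± 0.12, Gbx2 0.78 ± 0.14, Klf5 0.73 ± 0.09 and Bcl3 0.57 ± 0.21. These 6 were the members of the LIF/STAT3 list that rose, out of 13 tested, and 0 fell. Adjusted over the list alone, 8 rose. The list median was 0.39, above all random lists. Junb (0.21), Klf4 (0.39), Pim3 (0.23), Il6st (-0.05) and Cebpb (0.14) did not pass. The effect of Gbx2 in the fit was 1.38, larger than with LIF alone. The fit also draws on the other arrays, where Gbx2 was 3.23 with PCL, -0.93 with PD and 1.77 with CH.

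Only 7 of 7838 genes were at least 2-fold different with LIF, 2 higher and 5 lower. In the simulation 3.8 unaltered genes per run reached 2-fold for LIF by noise alone, so a part of the 7 may be noise. With the untreated array left out, so that the mean of PD and CH was the reference, there were 6 higher and 3 lower, sharing 1 gene with the 7. Against the median of the 3 arrays without LIF there were 2 higher and 1 lower, sharing 2. Besides Socs3, the higher one was Ahcy, the enzyme that hydrolyses S-adenosylhomocysteine (2.37-fold higher), which rose in the additive fit. It was also 0.75 higher with CH and 0.39 with PD. Ahcy was dim on the untreated array (log2 5.26, where the lowest detected level was 4.89). Without background correction its log2 difference with LIF was 0.60. Sp5 (0.85 ± 0.10), Irf1 (0.48), Lefty2 (0.34) and Esrrb (0.25) rose as well, while the list members Dppa5a (-0.28) and Gsc (-0.40) fell. The call of Esrrb leans on other arrays more than on LIF alone. Its effect in the fit was 0.54, and it was -0.55 with PD and 0.51 with PCL. The largest lower value with LIF among ERK targets was Egr1 (-1.30 ± 0.10), which fell with an additive effect of -0.50 ± 0.12 (SE of the fit, adjusted p = 0.00986). It was highest on the untreated array, departed from additivity by 2.15, was not lower with PCL (-3.62) than with PD (-3.68), and its LIF difference was 0.93 with the untreated array left out of the reference. Dusp4 (-0.91), Car11 (-0.96) and Fst (-0.86) were lower and did not pass. The FGF/ERK median was -0.12 (percentile 1.83), and Egr1 was its only member that fell, with 3 fallen and 1 risen when adjusted over the list alone. With the untreated array left out of the reference the median was 0.35. That reference holds the PD array, on which these targets were low. Neither 0.35 nor the 0.93 of Egr1 therefore measures a response to LIF. The 5 genes with the lowest adjusted p among those that fell were Nop10 (-0.61), Irgm1 (-0.50), the complex III subunits Uqcrb (-0.59) and Uqcrh (-0.51), and Ubl5 (-0.42). For Nop10 and Irgm1 another detected probe differed by -0.14 and 0.01. The Nodal/Activin and cholesterol synthesis lists lay above the random range without a matching set of calls. The Nodal/Activin list had a median of 0.23 (percentile 99.9) with Lefty2 as its only riser, and 2 rose and 1 fell when adjusted over the list alone. The cholesterol synthesis list had a median of 0.16 (percentile 99.5), and 0 of 11 members passed.

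The LIF term had 24 genes that rose and 45 that fell over all genes. Without the intensity trend in limma 14 rose and 14 fell, and on the authors' values limma passed 0 genes (473 at an unadjusted p under 0.05). After scaling to a common 75th percentile 6 genes were at least 2-fold higher and 6 lower.

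**Figure D2:**
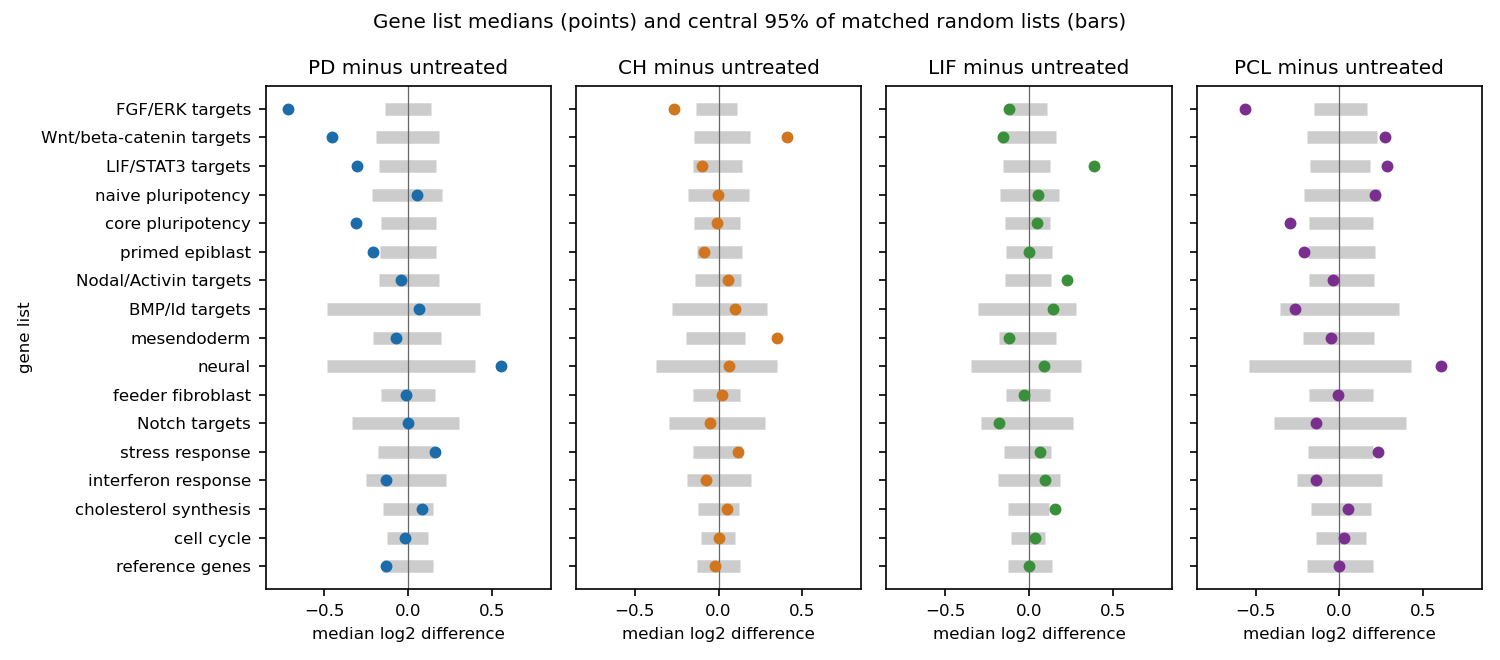
Median log2 difference from the untreated array (x axis) of each gene list (y axis) in the 4 comparisons, as points, with the central 95% of 10000 random lists matched on expression as bars. The FGF/ERK median lies at -0.71 with PD, the Wnt/beta-catenin median at 0.41 with CH and the LIF/STAT3 median at 0.39 with LIF, all outside the bars, while the feeder fibroblast median lies inside them in every comparison.

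The 3 agents together gave the most genes with a 2-fold difference, 89 of 7792, of which 29 were higher and 60 lower. Sp5 was 10.5-fold higher (log2 difference 3.40 ± 0.08), Gbx2 9.36-fold (3.23 ± 0.12) and Klf2 4.47-fold (2.16 ± 0.09). Also higher were Cdc42ep4 (1.57), Gadd45g (1.57), the Wnt receptor Fzd10 (1.55), Axin2 (1.52), Ahcy (1.49) and Socs3 (1.48). Egr1 (-3.62 ± 0.11), Dusp4 (-2.25 ± 0.09), Dusp6 (-2.00 ± 0.08) and Lbh (-1.87) were lower, as were the primed epiblast genes Pou3f1 (-1.81 ± 0.12) and Fgf5 (-1.79 ± 0.08). Otx2 was -0.94 ± 0.07 lower, while Fgf8 of the primed epiblast list was 1.39 higher. Arc was not detected with PCL and was at least 2.79-fold lower there.

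The FGF/ERK list had a median of -0.57 with PCL, below all random lists. The LIF/STAT3 list had a median of 0.28 (percentile 99.96) and the Wnt/beta-catenin list 0.27 (percentile 99.3). The core pluripotency median was -0.29 (percentile 0.28) and the primed epiblast median -0.21, also below the random range, while the naive pluripotency median of 0.21 (percentile 95.8) lay within the random range. Nanog was 0.88 higher and Klf4 0.75, and Sox2 was -0.56 lower. The mesendoderm median was -0.05, within the random range, with Gsc at 0.69, Mixl1 at 0.69, Eomes at 0.02 and Foxa2 at -1.25. The stress response median was 0.23 (percentile 98.8), and the neural median of 0.61 (percentile 99.3) again rests on Sox21 (1.43) and Nes (-0.22). Medians of the BMP/Id, Notch, interferon response, cell cycle and reference gene lists lay within the random range in every comparison. So did the feeder fibroblast list, at -0.01 with PD, 0.02 with CH, -0.03 with LIF and -0.01 with PCL. Its 11 detected members went both ways with PD, 5 above 0 and 6 below, but the falls were larger. They ranged from -0.60 to 0.26 with a mean of -0.13. The collagen Col6a1 fell (-0.58, adjusted p = 0.0224 in the limma fit) and Lum (-0.58) and Dcn (-0.48) were lower without passing. Thy1 (0.26) and Acta2 (0.20) were higher without passing. With scaling to a common 75th percentile 46 genes were at least 2-fold higher and 58 lower, and without background correction 10 and 20.

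Some genes in the combination were far from the sum of the single treatments. The untreated array enters this departure with a weight of 2, and the 4 largest departures, in Slc46a3 (2.79), Lor (2.27), Egr1 (2.15) and Car11 (2.07), were in genes highest on that array. Gbx2 and Fst, with smaller departures of 1.61 and 1.37, were not highest on the untreated array. They do not stand out in size among such genes. Larger departures were seen in Bst2 (-1.82) and, outside the rule for named genes, in Zfp459 (-1.99) and Kdm5b (-1.64). For Slc46a3, Lor, Egr1 and Car11 the single differences sum to -5.87, -4.43, -5.78 and -2.80. Added to the untreated level, each sum falls below 4.81, the lowest log2 level detected with PCL. A detected PCL level could therefore only depart upwards in these 4 genes, and their departures do not show an interaction of the agents. The differences of Gbx2 in the single treatments sum to 1.62, with PD at -0.93, against 3.23 with PCL. Fst was -1.67 with PD and 1.32 with CH, and it was 0.16 with PCL. With 1 array per condition these departures have no test.

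The direction of these differences was also looked at on arrays not used to choose the genes. PCL minus any single treatment holds the effects of more than 1 agent, so the shares below do not isolate an agent, and an even split is not the value to be met without an effect. Of the 61 genes at least 2-fold different with PD, 59 had the same direction in PCL minus CH, 57 in PCL minus LIF and 59 (96.7%) in PCL minus the mean of both. Of the 15 genes of CH, 14 had the same direction in PCL minus PD, and 15 in PCL minus LIF and in PCL minus the mean of both. Of the 7 genes of LIF, 5 had the same direction in PCL minus PD, and 7 in PCL minus CH and in PCL minus the mean of both. Egr1 is 1 of the exceptions for LIF, since it was -3.62 with PCL and -3.68 with PD. Grm6 is the other, and it was not detected with PD. Across the 6821 genes detected on all arrays, Pearson's r between a single treatment's difference and PCL minus the mean of the others was 0.33 for PD, 0.35 for CH and 0.21 for LIF, and Spearman's rho was 0.15, 0.28 and 0.15. These are 3 correlations across genes, which are not independent replicates. At 1.5-fold, 318 of 407 genes with PD, 166 of 221 with CH and 87 of 128 with LIF had the same direction as PCL minus the mean of the others.

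**Figure D3:**
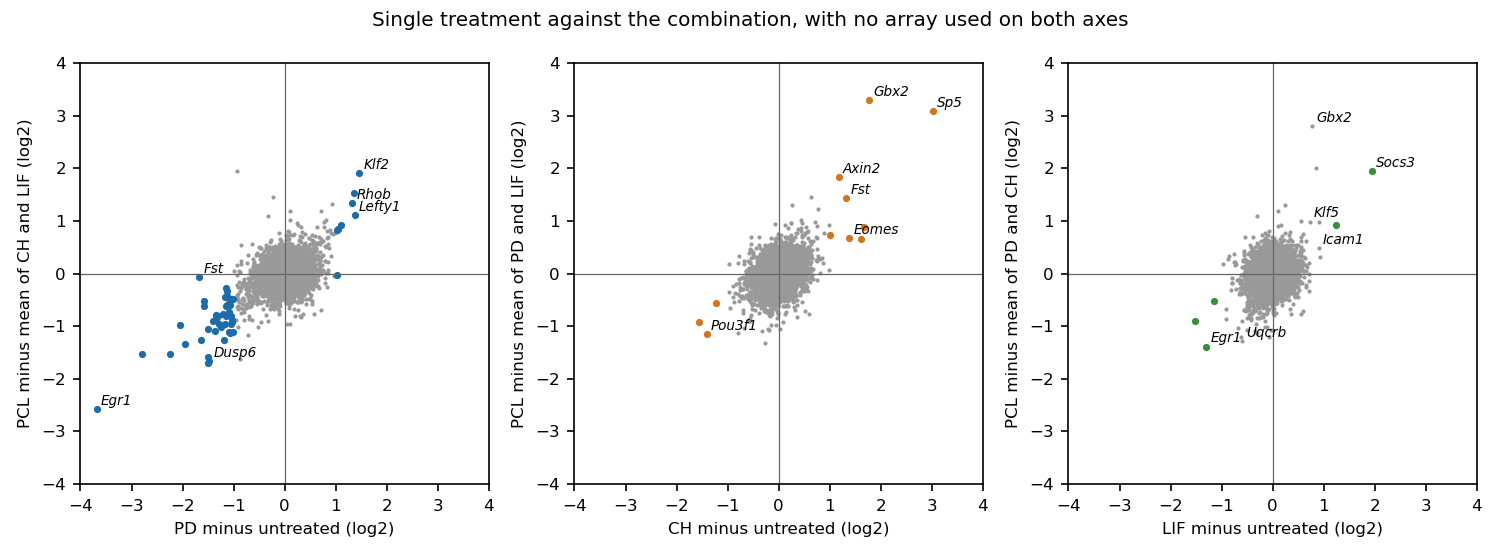
Log2 difference between a single treatment and untreated (x axis) against PCL minus the mean of the other single treatments (y axis), with 1 point per gene detected on all 5 arrays and coloured points for genes at least 2-fold different on the x axis. Sp5 lies at 3.03 in the CH panel and Egr1 at -3.68 in the PD panel, and across genes Pearson's r is 0.33 for PD, 0.35 for CH and 0.21 for LIF.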

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

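The reference that leaves out the untreated array was chosen after the data had been seen, and the other alternatives before. No paired analysis was possible because each group has 1 array, so no replicate could be left out either. The additive fit without the untreated array leaves no residual degree of freedom. Signals of the 75th percentile were only 1.80 to 2.25 times the median of undetected probes, so small differences of dim genes are limited by background.

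Counts of genes at least 2-fold different moved by over 1.5 times from the main 61, 15, 7 and 89 for PD, CH, LIF and PCL. Without background correction they were 24, 6, 3 and 30, and with an offset of 50 they were 29, 9, 3 and 40, where a larger constant under each signal shrinks folds by construction. Scaling to a common 75th percentile gave 92, 37 and 12 for PD, CH and LIF, and the authors' values gave 135, 46, 32 and 166. The cause was not tested for these. At 1.5-fold they were 407, 221, 128 and 488. Against the median of the 3 arrays without the agent, the counts were 39 for PD and 3 for LIF. Lists outside the random range numbered 7, 3, 4 and 7. With no detection filter this was 4 for PD and 4 for PCL, without background correction 4 for PCL, and with the untreated array left out 6 for CH.

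In the additive fit the authors' values gave 0 genes for PD, 0 for CH and 0 for LIF with limma, against 251, 130 and 69, with 630, 674 and 473 at an unadjusted p under 0.05. There the prior degrees of freedom were 0.842 and not infinite. The CH count was 58 after scaling to a common 75th percentile, 51 with no detection filter, 75 without a trend and 213 at an adjusted p under 0.1. The LIF count was 43 with no detection filter and 28 without a trend. In these 2 settings the prior degrees of freedom were 32.5 and 32.7. The share of PD genes with the same direction in PCL minus the mean of CH and LIF, which also holds effects of those agents, was 100% of fewer genes without background correction and 100% with an offset of 50, 82.2% in the authors' values and 78.1% at 1.5-fold. For CH it was 75.7% after scaling, 76.1% in the authors' values and 75.1% at 1.5-fold.

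Directions turned mainly where the untreated array was left out and the mean of the other single treatments was the reference. That reference contains the PD or CH array by construction. The FGF/ERK median became 0.43 for CH and 0.35 for LIF, Slc46a3 and Lor became 0.59 and 0.36 for CH, and for LIF Bst2 became -0.27, Sp5 -0.54, Egr1 0.93, Grm6 0.61 and Dusp4 0.47. The FGF/ERK median for CH was also 0.13 against the median of the 3 arrays without CH. The PCL neural median was -0.022 with no detection filter, where genes without signal enter the list. Few turns could occur among the 89 named gene values, because most were chosen for large differences and these settings rework the same arrays. Of these values, 0 changed direction with another offset, scaling, background or probe choice, or in the authors' values. Their sizes did move, with 313 of the values of named genes over all settings labelled as moved, 263 as the same and 7 as reversed. Egr1 with PD was -2.92 without background correction and -3.96 in the authors' values against -3.68, and Mixl1 with CH was 0.89 and 2.20 against 1.67.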

Other observations

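All tests in this part were chosen after the results they concern had been seen. Earlier tests of an intensity-dependent difference (which had left it open), of the LIF array and of RNA quality were replaced, and the limit for the feeder list was changed, after their results were known.

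Genes that stood apart on the untreated array were counted. On that array 11 genes lay at least 1.5-fold above all 4 others, among them Slc46a3, Lor, Grm6, Zfp467, Egr1 and Car11, and 2 lay below, Bst2 and Ankrd17. Genes in this paragraph that fall outside the rule for named genes, such as Ankrd17, were picked after their values were seen. Slc46a3 was -2.79, -1.56, -1.51 and -3.07 with PD, CH, LIF and PCL. The PD array had 19 genes at least 1.5-fold below all others and 2 above, Tmem254a and Gstm1. The CH array had 9 above, led by Eomes, Fst and Mixl1, and 1 below, Kcnh2. The LIF array had 1 above, Icam1, and 2 below, Adarb1 and Ubtd1. The PCL array had 10 above, led by Gbx2, and 12 below, among them Arc, Fgf5, Tomm7 and Uqcrb. Among unnamed probes, 2 were at least 2-fold different with PD, 2 with CH, 0 with LIF and 5 with PCL.

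The first pattern is that genes lower with PD were also lower in the CH and LIF arrays than in the untreated array. To keep the untreated array out of the choice, genes at least 1.5-fold lower with PD than with LIF were taken (121 genes), and their median CH minus untreated difference was -0.11 (percentile 0 of the matched random lists), so random noise of the untreated array alone is argued against. More feeder cells in the untreated sample remain open, because the 10 feeder list genes detected on all arrays went both ways (median 0.0265 in CH minus untreated, SD 0.147, and median 0.0146 in LIF minus untreated, SD 0.159), and Lum (-0.33) and Dcn (-0.25) were lower with LIF. Genes higher with PD did not show the converse, with medians of -0.01 in CH minus untreated (percentile 64.4) and 0.03 in LIF minus untreated (percentile 95.6), both inside the random range. That ERK signalling was higher in the untreated culture is an untested hypothesis for the lower genes only, and an untreated culture or RNA that differed for a reason other than the agents (LIF minus untreated median -0.16 for the 145 genes lower with PD than with CH) cannot be told apart from it with 1 untreated array.

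The second pattern is that genes of a few families made up 15 of the 45 genes that fell with LIF. The families were ribosomal proteins, the respiratory chain, ATP synthase, mitochondrial import and small ribonucleoproteins. They were chosen by symbol after that list was seen. Whether an intensity-dependent difference between arrays has a part cannot be decided from genes of like intensity outside the families. The 100 nearest in expression to each of the 15 genes had a median additive LIF effect of at least 0.00351. It was -0.39 or lower in the 15. Quantile normalization holds such medians near 0 by construction, and the 15 genes were chosen because they fell. Lower values on the LIF array alone would make PCL depart upwards from the sum of the single treatments, but the median departure of the 15 genes was -0.41, so an oddity of that array alone is argued against, and the other genes that fell with LIF departed alike (-0.46). The 15 genes were also higher with PD than with CH (median 0.40), arrays without LIF, so an oddity of the PD or the PCL array cannot be told apart from an effect of the agents with 1 array per condition. Nor can RNA or amplification quality differing between the 5 samples (median of the 240 family members detected on all arrays 0.0932 with PD, -0.10 with PCL and, inside the random range, -0.02 with LIF), and no biological explanation was tested.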
